A study of Homo sapiens with 259 samples.

How the data were processed

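Human ovary tissue from 2 sources was profiled with NanoString GeoMx, an assay in which oligonucleotide probes bind RNA in a tissue section and the barcodes of the probes are released by light from chosen areas and sequenced. The labels name each sample by its source and an area number, and give no region type, cell type or marker by which an area was chosen. The series' title speaks of morphology as the guide to the areas. A single-cell part of the study is named in the series' design and was not analysed here. Source 1 had 94 areas on 1 collection plate and source 2 had 165 areas on 2 plates, with 95 areas on plate 1 and 70 on plate 2. The plates are numbered here by the order of their identifiers in the file headers. Per the file headers, no plate and no sequencing run held areas of both sources.

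Each deposited file holds 1 area, with a whole-number count per probe identifier (RTS number). Per the file headers, the counts were made by the GeoMx NGS Pipeline version 2.3.3.10, and they are counts of unique molecular identifiers left after duplicate reads were merged. A probe with no count has no line in a deposited file and was set to 0. In 49 of the 259 deposited files the unit of the same field was recorded as other, because the unit check could not reach that field there; these files hold the same whole counts of at least 1. Per the submitters' processing notes, the genome build was GRCh38. The fixation, the probe set and the chemistry are not given in the sources used here. The deposited counts are whole numbers with a different total in each area, and no normalisation of them is stated.

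The files do not pair the 18815 probe identifiers with genes, and the reference table used here holds no probe identifiers, so 0 probes were matched to a gene. The cell type marker lists and the list pairs fixed before the data were examined were therefore not used. The rule for named items, also fixed before the data were examined, then allowed the 2 highest and the 2 lowest probes of each comparison. No probe is named for the comparison between sources, and no level of a probe in a source is given, because probes that report on a personal trait cannot be set aside without gene names. For the plates of source 2 only ratios are given, and for the spread across areas only spreads.

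Counts were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. An area entered the analysis with at least 1000 raw reads and a sequencing saturation of at least 50%, where saturation is 100% minus the deduplicated counts as a percent of the aligned reads. All 259 areas passed. For a level, counts were summed over the areas of a source or plate and expressed as CPM (counts scaled to one common total), and the log2 ratio of 2 sums was taken. A probe counted as above background when its CPM was at least 2 times that of the median probe in at least 1 of the 2 sums compared. The median probe served as the background because negative probes cannot be told from the others without a probe table. The level of a probe thus includes background, which draws ratios of weak probes towards no difference. A probe was called 2-fold different at a log2 ratio of at least 1 in size. Intervals of a ratio came from exact 95% binomial intervals of how the count of a probe splits between the 2 sums. They cover counting error only.

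Each source was taken as 1 donor, and an area is not a replicate of a source. No test between sources was made and no p-value is given for one. The plates of source 2 were compared in the same way, as a yardstick for how far sums over different areas of 1 source differ. Spread across areas was the 90th minus the 10th percentile of log2(scaled count + 1), with each area scaled to its 75th percentile of probes. The spread that counting noise alone gives was simulated from each probe's mean share. Intervals of spread results are the 95% range of 100 resamples of the areas. Such resamples treat areas as exchangeable, and are too narrow where neighbouring areas are alike.

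Co-variation of probes was added after the lack of gene names was seen. Spearman correlations across areas were computed for every pair of the probes above background in each source. Probes were joined by average linkage at a correlation of 0.5, and groups of at least 10 probes were kept. The median pairwise correlation of a group was then measured in the other source and ranked among 1000 random groups of the same size matched on level in 10 bins. Other settings were trimmed-mean (TMM) factors from edgeR 4.0.16 in R 4.3.3, the 75th percentile of the sums, the median or mean over areas, other background filters, areas thinned to 50000 counts (leaving out the areas with fewer, 2 of source 1 and 6 of source 2) and single plates. The median probe was also subtracted before taking ratios, and single areas were left out. The choices made only after the data were examined are named with their values.

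The steps were tested on simulated data. For sums over areas, counts of 18815 probes were drawn with the real depths and counting noise, from 1 share per probe in all areas of a source. The changes were put on the whole count, background included. Of probes changed 3-fold, 50 in each direction, 100% were called. Of probes changed 1.5-fold, 50 in each direction, 0% were called, as were 0% of 1338 unchanged probes. For co-variation over 1538 probes, 5 of 5 simulated groups were recovered, and 0 groups were found where no factor was shared. Apart from the shared factors, the simulated areas of a source differed by depth and counting noise only. The 0% and the 0 groups therefore cover counting noise and not real differences between areas.

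The total count per area ranged from 15640 to 4486543, with a median of 377045. The median probe of an area held a median of 15 counts, so that counting noise is large for a single probe in a single area and small for sums over areas, in which every probe above background had at least 2338 counts in source 1 and 2780 in source 2. The areas with the highest correlation between their probe counts (0.950) still differed by more than sampling noise, at a chi-square of 2.53 per degree of freedom, and no pair was treated as 1 library.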

Results

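The data are probe counts from 259 captured areas of human ovary, 94 from source 1 and 165 from source 2. The total deduplicated count per area had a median of 433374 in source 1 (range 15640 to 4486543). In source 2 the median was 287281 (range 16384 to 3415385), with 241691 on plate 1 and 513067 on plate 2. Median sequencing saturation was 66.8% in source 1, 82.7% on plate 1 of source 2 and 88.8% on plate 2. Of the 18815 probes, 1247 were counted in every area, and 121 areas had a count for every probe. Fewer than 50000 counts were present in 2 areas of source 1 and 6 of source 2.

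**Figure D1:**
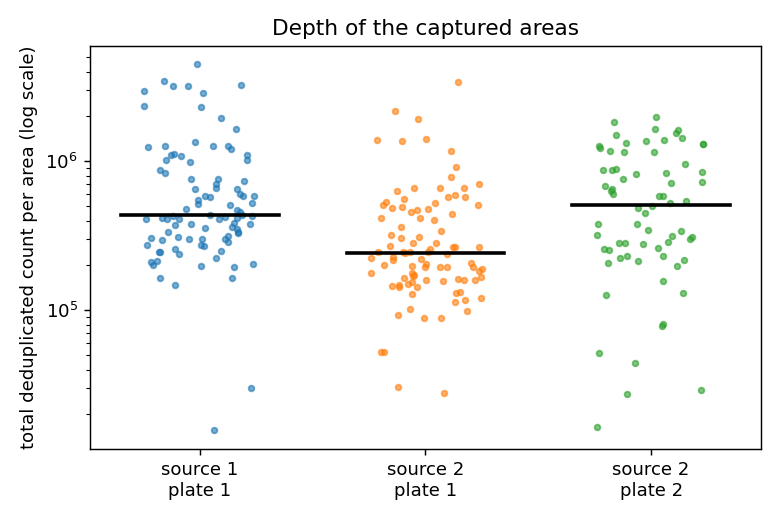
Total deduplicated count of each of the 259 areas (log scale), by source and plate; each point is 1 area and the bar is the median. The medians are 433374 in source 1, 241691 on plate 1 of source 2 and 513067 on plate 2, and each plate spans more than the differences between these medians.

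The first comparison sets the level of each probe in source 1 against source 2. Of all probes, 1538 (8.17%) lay above background in at least 1 source, 863 in source 1, 1494 in source 2 and 819 in both. Most probes thus lay close to the median probe. Among the 1538 probes, 5 were at least 2-fold higher and 42 at least 2-fold lower in source 1, and the median log2 ratio was -0.28 (5th to 95th percentile -0.85 to 0.25). Over all 18815 probes the median log2 ratio was 0.15. The 1538 probes held 20.0% of the counts in source 1 and 26.6% in source 2. More of them entered through source 2 alone than through source 1 alone. This choice can lower their median ratio and raise their share in source 2. Without the background filter, 6 probes were 2-fold higher and 42 lower in source 1. The 99th percentile probe stood at 3.83 times the median probe in source 1 and at 6.12 times in source 2.

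The summed log2 CPM of these probes correlated between sources at a Pearson r of 0.900 and a Spearman rho of 0.744, across probes, which are not independent replicates. For all 47 probes called, the counting interval of the ratio excluded no difference. Sums this large bring that about for any 2-fold ratio, so it adds no support beyond the call. With 1 source per group there is no replicate check, and source, plate and sequencing run cannot be told apart. Against source 2 as a whole and each of its plates alone, 4 probes were 2-fold higher and 21 lower in source 1. Against plate 1 of source 2 alone 14 were higher and 120 lower, and against plate 2 alone 5 and 34. Subtraction of the median probe from each sum, with the excess scaled to 1 sum, gave 75 probes higher and 59 lower. The median over areas gave 2 higher and 21 lower, and the mean over areas 14 and 32. TMM factors gave 3 and 70, and areas thinned to 50000 counts gave 13 and 34, or 72.3% lower against 89.4% in the summed counts. Over 20 thinnings the share lower was 62.8% to 72.3%, with a median of 68.9%.

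The second comparison sets plate 1 of source 2 against plate 2, that is, different areas of 1 source. Of 1803 probes above background on at least 1 plate, 88 were at least 2-fold higher and 7 at least 2-fold lower on plate 1, 95 in all (5.27%) against 47 of 1538 (3.06%) between the sources. Between source 1 and plate 1 of source 2 alone the number was 134 (7.78%), and with plate 2 alone 39 (2.73%). The counting interval excluded no difference for all 95, which again follows from the size of the sums. Between sources and between plates, 17 probes were 2-fold apart in both comparisons, against 2.96 by independence. The counts of source 2 enter both, so the comparisons are not independent. Over the 1538 probes of the first comparison, the correlation of summed log2 CPM between plates was 0.867 (Pearson) and 0.705 (Spearman), across probes. Probe RTS0049721 had the highest ratio, 7.62-fold higher on plate 1 (log2 2.93, counting interval 2.85 to 3.01), and RTS0050832 followed at 7.52-fold (log2 2.91, 2.84 to 2.98). For both, 5 areas held most of the plate 1 count, 61.5% for RTS0049721 in areas with 18.1% of all counts of the plate, and 68.3% for RTS0050832 in areas with 18.5%. The medians over areas of these probes differed between plates by log2 0.16 and 0.24. The lowest ratios were those of RTS0051029 (log2 -1.24, -1.29 to -1.18) and RTS0023133 (log2 -1.18, -1.24 to -1.12), whose area medians differed by -1.03 and -0.79.

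With the median over areas in place of sums, 0 probes were higher and 5 lower on plate 1, and with the mean over areas 52 and 0, which is 2.88% of the probes against 2.99% between the sources. Without area 52 of source 2, which held 8.92% of the plate 1 counts, 58 probes were higher and 4 lower.

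**Figure D2:**
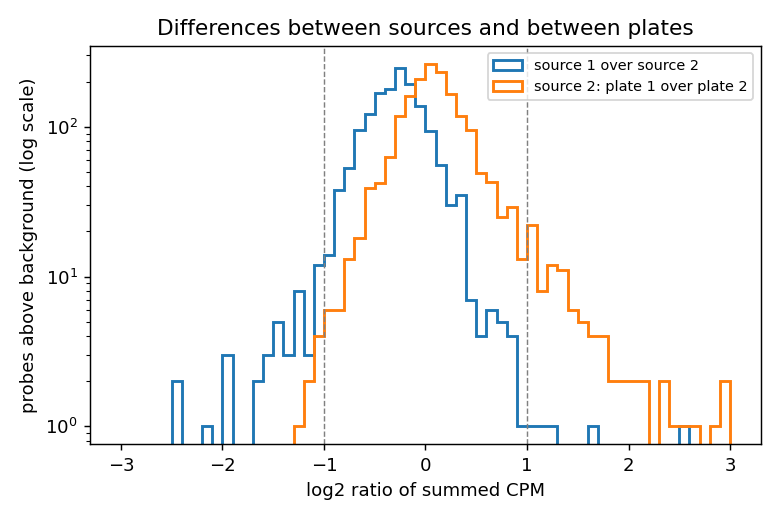
Number of probes above background (log scale) by log2 ratio of summed CPM, for source 1 over source 2 (1538 probes) and for plate 1 over plate 2 of source 2 (1803 probes). Dashed lines mark 2-fold. More probes lie beyond them on the lower side for the sources (5 higher, 42 lower) and on the higher side for the plates (88 higher, 7 lower). The ratios ran from -2.48 to 2.51 for the sources and from -1.24 to 2.93 for the plates.

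The third comparison asks which probes differ most between areas, and whether both sources rank them alike. Among the 819 probes above background in both sources, the spread between the 10th and 90th percentile area had a Spearman rho of 0.827 between sources (95% range of resampled areas 0.753 to 0.834) and a Pearson r of 0.773, across probes. The median spread was log2 1.21 in source 1 and 1.31 in source 2, a difference of 0.10 whose resampled range, -0.02 to 0.23, includes 0. Counting noise alone gave median spreads of 0.49 and 0.60, and 786 of the 819 probes exceeded it in both sources. The 17277 probes not above background had median spreads of 0.91 and 1.18, against 0.79 and 1.10 from counting noise. A spread of at least 2 was found for 173 probes in source 1 and 135 in source 2, with 90 in both against 28.5 by independence. The value by independence and the correlations of spreads take no account of the level of a probe, on which its counting noise depends.

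Ranked by the lower of its ranks in the 2 sources, RTS0050848 had the widest spread, with log2 5.11 in source 1 and 4.10 in source 2, a 34.6-fold and a 17.1-fold range over areas. RTS0050722 followed with 4.31 and 4.70, or 19.8-fold and 25.9-fold; within source 2 its spread was 5.46 on plate 1 and 2.07 on plate 2. The narrowest by the same rule were RTS0029548 (0.48 and 0.66) and RTS0038126 (0.46 and 0.71). Counting noise alone gave 0.44 and 0.68 for RTS0029548 and 0.49 and 0.73 for RTS0038126, so that their spread was about that of counting. With areas thinned to 50000 counts, and the 2 areas of source 1 and 6 of source 2 with fewer left out, the agreement of the sources was lower (rho 0.542) and the difference of median spread was -0.24. Thinning raised the median spread to 1.85 in source 1 and 1.61 in source 2, and that of RTS0029548 to 1.66 and 1.34. No spread from counting noise is given for thinned areas, so the thinned values do not show how far spread beyond counting depends on depth.

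**Figure D3:**
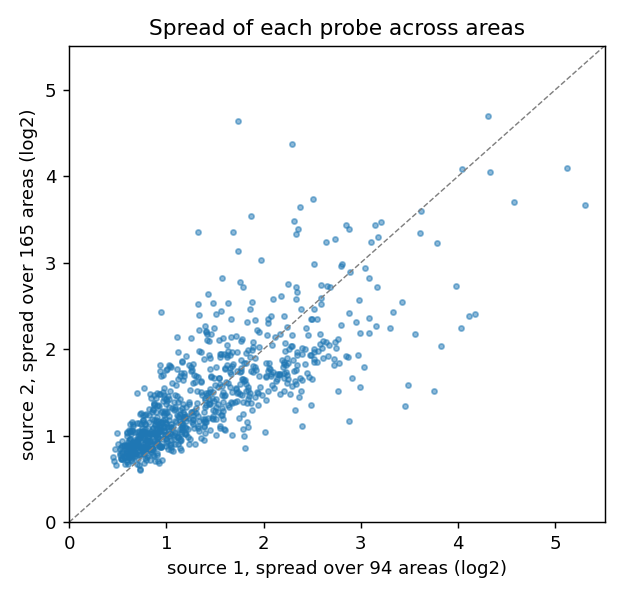
Spread of each of the 819 probes across the 94 areas of source 1 (x axis) and the 165 areas of source 2 (y axis), as the 90th minus the 10th percentile of log2 scaled counts; the dashed line marks equal spread. Probes wide in one source tend to be wide in the other (rho 0.827).

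The last comparison asks whether probes that rise and fall together over the areas of one source do so in the other. Over the 1181953 pairs of the 1538 probes, the Spearman correlations in source 1 and source 2 were related at a Pearson r of 0.571 (lowest and highest of 20 resamples of the areas 0.470 and 0.603), against 0.497 between the plates of source 2. Pairs correlated at 0.7 or more numbered 66138 in source 1 and 14177 in source 2, with 9862 in both against 793 by independence. Pairs at -0.5 or less in both numbered 212 against 12.5. Pairs share probes and independence takes no account of their level, so these numbers only describe the overlap.

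In source 1, 868 probes fell into 10 groups of 10 to 672 probes. In source 2, 880 probes fell into 16 groups of 10 to 227. Of the 10 groups found in source 1, 8 had a median pairwise correlation in source 2 above the 95th percentile of random groups matched on size and level. The group of 672 probes had a median correlation of 0.63 in source 1 and 0.34 in source 2, where matched random groups had 0.20. A group of 39 probes had 0.61 and 0.59, with 0.24 for random groups, and a group of 14 had 0.55 and 0.51, with 0.15. The groups of 23 and 18 probes, at 0.29 and 0.18 in source 2, lay below their 95th percentiles of 0.32 and 0.23. Of the 16 groups found in source 2, 13 lay above the 95th percentile in source 1, among them a group of 198 probes at 0.71 against a random median of 0.39. Of the 10 groups of source 1, 8 lay above it on plate 1 of source 2 alone and 5 on plate 2 alone. The genes of these groups are not known here.

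**Figure D4:**
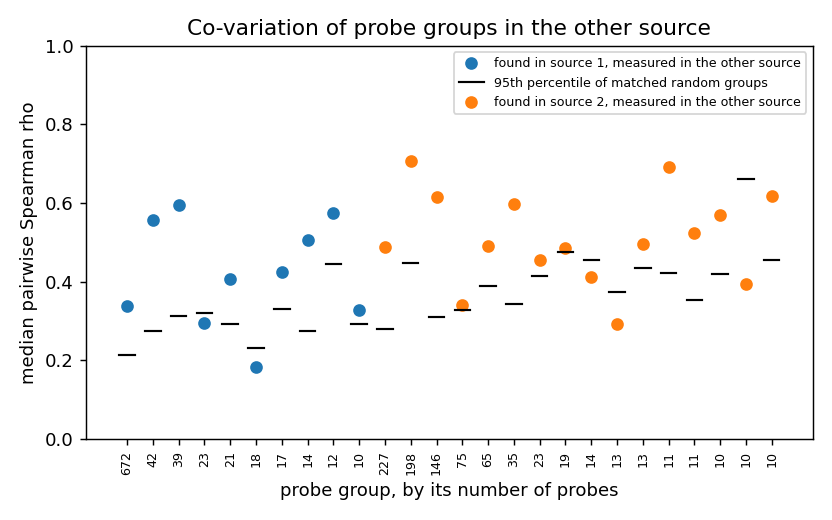
Median pairwise Spearman correlation of each probe group in the source in which it was not found, with the number of probes on the x axis; the black line is the 95th percentile of 1000 random groups matched on size and level. Of the groups found in source 1 (blue), 8 of 10 lie above their line, and of those found in source 2 (orange), 13 of 16.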

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

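Chosen after the data were examined were the subtraction of the median probe, the mean over areas, the single areas left out, the thinning of plates and spreads, and all co-variation settings; all others were planned. Of 64 values under other settings, 38 stayed within their bounds and 26 moved; where they moved, the cause was not tested. Between sources, against 5 probes higher and 42 lower in source 1, the median over areas gave 2 and 21, TMM factors 3 and 70, plate 1 of source 2 alone 14 and 120, a filter at 4 times the median probe 3 higher, thinned areas 13 higher, the subtracted median probe 75 higher and the mean over areas 14 higher. More probes stayed lower than higher in source 1 under each of these except the subtraction of the median probe (75 and 59). Each area left out in turn gave 4 to 5 higher and 31 to 44 lower. Between plates, against 88 higher and 7 lower, the median over areas gave 0 higher, thinned areas 57 and 3, the subtracted median probe 180 and 81, and the mean over areas 52 and 0. Each area left out gave 58 to 92 higher and 4 to 8 lower, and area 52 of source 2 alone gave the 58 and the 4. The agreement of spreads, a rho of 0.827, was 0.628 with the standard deviation and 0.542 with thinned areas, where the difference of median spread turned from 0.10 to -0.24. The correlation of probe pairs, 0.571, was 0.404 with thinned areas, 0.457 with plate 1 of source 2 alone, where 8 groups passed, and 0.608 with plate 2 alone, where 5 in place of 8 passed. The area filter removed no area, so that setting tests nothing. The planned settings for list levels, list co-variation and relations between lists were not run, since no probe has a gene name here. Depth limits single areas, whose median probe held 15 counts. No paired analysis was possible because the area numbers shared by the sources name areas only and each group is 1 source. The values of this section come from no test with a p-value.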

Other observations

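The tests of weaker signal, of deep areas and of a minority of areas were chosen after the results were seen. So were the thinning tests for the plates and for probe groups, and the repeats of the thinning. The use of percents between plates and the blocks of probe numbers were also chosen then. The other tests were set down before their results. Random splits treat areas as exchangeable, which the last hypothesis speaks against.

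More probes were lower (42) than higher (5) in source 1. A weaker signal over background in source 1, taken as 1 factor of 0.646 on the excess over the median probe, stays open: 13 probes lay 2-fold below and 8 above the level it predicts, or 61.9% below (exact 95% interval 38.4% to 81.9%) against 89.4% before, but the factor was set to the median of the probes and 21 probes are too few to decide. Depth also stays open, because the thinned areas had 72.3% lower, between the bounds of 65 and 75 set for a decision, and 20 thinnings gave 62.8% to 72.3%, on both sides of the lower bound. Thinning also gives every area equal weight. The mean over areas, with equal weight and no thinning, had 69.6% lower, so the test cannot separate depth from the weight of the areas. Sequencing run and source cannot be told apart, with 0 runs that held both, and a biological difference between the sources was not tested.

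The plates of source 2 differed in more probes (95, or 5.27% of those compared) than the sources did (47, or 3.06%). These sums cover unequal numbers of areas, and source 2 as a whole joins both plates. Against plate 2 alone, source 1 differed in 39 probes (2.73%), but against plate 1 alone in 134 (7.78%), more than the plates did. The pattern thus depends on which areas are summed. Depth stays open: thinned areas gave 60 probes (3.53%) between plates and 47 (3.09%) between sources. Here too thinning gives every area equal weight, which the test cannot separate from depth. Of 20 thinnings, the count was larger between plates in 20 but the percent in 17. A decision needed the same direction for count and percent in every thinning, because the numbers of probes compared were unequal. The mean over areas left 52 (2.88%) against 46 (2.99%), under the 1.5 times set for a decision, so a few deep areas cannot be told apart from other causes; the median over areas left 5 against 23, as a minority of areas on plate 1 with high values would give. Only 1 of 100 random splits of the areas, the real one, reached 95 (highest other 25), yet of 63 splits that kept the areas in order and moved the border, 28 reached it (highest 153). Neighbouring areas that are alike are therefore a candidate explanation, and whether plate handling or the choice of tissue parts lies behind them was not tested.

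Probe groups found in source 1 also co-varied in source 2 (8 of 10). Unequal totals of the areas are argued against as the cause of the excess over random groups only. Thinning makes the totals equal but keeps the shares of probes within an area, so traits that go with depth stay open. With areas thinned to 50000 counts, at least 9 of 10 groups lay above the 95th percentile of matched random groups in each of 5 thinnings. Of the 8 above as found, 7 to 8 stayed above. Thinning lowered the correlation of probe pairs from 0.571 to 0.404. A correction for the log total count hardly moved that correlation (0.561) and decides nothing. Given the share of counts in probes above background, 10 of 10 groups were above the 95th percentile, among them the 8 above as found. This argues against that share as the cause of the excess over random groups only. The random groups and the share come from these same probes, so the correlations themselves are not explained by it or freed of it. The correlation of probe pairs was 0.508 given the share. Shared probe chemistry and cell types common to both tissues stay open, and neither was tested without gene names.

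A further hypothesis is that areas with neighbouring numbers share a position, collection order or plate well. Consecutive areas correlated at a mean r of 0.448 in source 1 and 0.414 and 0.404 on the plates of source 2, in centred log2 values. Over all pairs the mean was 0.00 to 0.01, which the centring itself brings about, so the shuffled order is the yardstick. The permutation p was 0.0001 on each plate, the smallest that 10000 shuffles can give, and the highest shuffled mean was 0.155. The test does not separate position from collection order or well, and whether neighbouring areas share depth was not tested.

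In 1 area of source 1, 11.4% of 4221154 reads aligned, where the next lowest area had 80.0%. The share of probes above background differed between blocks of probe numbers, and the extremes were picked after their values were seen, among the 20 blocks with at least 500 probes. In the highest block, RTS0026000 to RTS0026999, 188 of 868 lay above background (21.7%), and in the lowest, RTS0036000 to RTS0036999, 17 of 918 (1.85%). Over all 24 blocks of 1000 numbers the chi-square was 625, against a highest of 51.8 in shuffled numbers (permutation p of 0.0001, the smallest 10000 shuffles can give).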
